A study of Mus musculus with 122 samples.

How the data were processed

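Ribosome profiling maps the stretches of mRNA that ribosomes protect from nuclease, so that the number of protected fragments (footprints) on a coding sequence counts the ribosomes on it. The 122 samples came from C57BL6 mice and comprised 24 mRNA libraries (8 organs, 3 animals each) and 98 footprint samples. Of the footprint samples, 21 came from untreated animals (9 organs), 51 from run-off experiments and 26 from animals given harringtonine for 5 or 30 min. Harringtonine stops ribosomes as they start a coding sequence and leaves those already elongating to move on. In the run-off experiments it was injected into the tail vein and elongation was stopped with cycloheximide 15, 30, 45 or 60 s later, so that the start of each coding sequence emptied with time. Per the labels, run-off was done in liver, kidney and skeletal muscle of young mice (13 to 15 weeks) and in liver of old mice (72 weeks, up to 45 s). The design text names heart, kidney and skeletal muscle at 15 and 72 weeks with 3 time points, which differs from the labels. The labels were followed. The sex of the animals is not given in the sources used here.

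The submitters' processing notes name cutadapt, TopHat, TopHat2 2.1.0, HTSeq and the genome build GRCm38.p3, without the role or order of the tools. Per the labels' protocols the footprints were cut from a gel at about 28 to 30 nucleotides. Muscle was pulverised in liquid nitrogen and lysed in another buffer than liver and kidney, and pancreas and spleen were digested with RNase T1 alone. mRNA of liver and kidney was purified on columns, and mRNA of the other organs with Trizol and columns. The deposited count tables hold raw read counts per gene symbol, 1 table for untreated footprints and 1 for mRNA, with 24336 rows each, of which 0 lacked a gene. The deposited signal files hold, for each coding sequence, the read coverage at each nucleotide with 100 nucleotides on each side, 1 file per run-off library and per untreated library. Of the 8 long harringtonine files, 7 pooled 3 or 4 animals. The coverage carried no normalization, so a sum of coverage was divided by 28 to give footprint equivalents. Files of old liver list 17957 coding sequences and those of young animals 13685.

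Replicates are animals: the labels give each library an animal number, and the same number in several organs is the same mouse. Fits with the animal as a block were therefore alternatives to the fits without it. Same-animal correlations of residuals, between liver and kidney or muscle libraries of the same assay, lay between -0.00 and 0.11. The name of 1 untreated spleen footprint column matched its group and no single sample, so this library entered fits of its group and was left out of fits with the animal block. In the count tables and the liver run-off libraries at 15 to 45 s, the 67 pairs of replicates differed by more than sampling noise (chi-square per gene 2.77 to 80.3), and 0 held identical values. Pairs of kidney and muscle run-off and of liver at 60 s were not compared. No column of per-sample values was left unused (0).

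The test of each comparison, the samples in it, 49 gene lists, the rule for named genes and all alternatives but those said to be chosen later were fixed before the data were examined. For run-off, coding sequences of 700 codons or more with at least 50 footprints between codon 500 and 20 codons before the stop were each divided by their mean in that window. Values were capped at 10, averaged over transcripts with equal weight and smoothed over 25 codons, leaving out codons before 10. A library needed 10 passing transcripts, a minimum lowered from 20 because 1 library of the low-abundance class of young liver had 12. The run-off position was fixed as the codon, from codon 20 on, at which this profile reached 0.5. With that rule 30 of the 41 libraries at 15 to 45 s met the level at codon 20, the lowest searched, so it was not relied on alone. The report therefore gives the values of the fixed rule and of the 2 other positions listed at the outset. These were the same crossing after dividing the profile by that of untreated libraries of the organ (the divided position), and the area by which the profile lay below 1 (the missing area, clipped at 0 after its signed form had been seen). The slopes of 7 position measures were seen before these measures were settled. The divided profile of old liver used untreated young liver. On simulated run-off with rates of 4 and 6 codons per s, divided positions gave 3.97 to 4.06 and 5.96 to 6.00, and missing areas 2.84 to 3.44 and 4.70 to 5.13. That simulation used the same untreated profile and an assumed lag and left-behind share, so it favours the divided position by construction.

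Rates are least-squares slopes over 15, 30 and 45 s, tested by permuting times (exact under 10 libraries, otherwise 100000 resamples). Differences between slopes were tested by exact permutation of group labels within times, with Benjamini-Hochberg adjustment over 4 differences. A constant offset of position between groups, such as a different delay before the drug acts, widens the null of this test, so it is conservative. Removing group means before permuting is given as an alternative. Its p is approximate, since the means are estimated from the same libraries. Transcript classes of high and low footprint abundance were compared by exact sign flips of the class labels within libraries. A constant offset between the classes widens the null of this test as well. All tests were two-sided.

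Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr by group, R 4.3.3) with 1 coefficient per organ, and translation efficiency as the interaction of assay and organ in 1 model over both kinds of library. Standard errors of log2 fold changes are the fold change divided by the square root of F. Coverage sums are not whole counts, so the age comparisons used the planned fallback, limma 3.58.1 on log2 CPM with a prior count of 2, in place of edgeR. Footprints were summed from codon 350 on (coding sequences of 450 codons or more, 21 libraries, time as a factor; 5611 genes in both sets of files, 5180 with the same coding length) or from codon 100 on at 15 s (150 codons or more; 11934 genes, 11113 with the same length). The false discovery rate (Benjamini-Hochberg) was 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of each comparison. The 38 list results described were chosen after the list tests had been seen. Named genes are, per comparison, the 5 highest and 5 lowest log2 fold changes among called genes with a mean log2 CPM of 5 or more and groups that do not overlap, without predicted genes and pseudogenes; up to 4 called members of each described list with the largest absolute change, or the 2 most abundant where none was called; and Eef1a1, Eef1a2, Eef2 and Eif5a. Some genes that the rule takes are not reported here. A fold against a group with 0 counts is a lower bound against 3 counts over that group's libraries together, at TMM-normalized library sizes (0.136, 0.109 and 0.206 footprint CPM in liver, kidney and muscle, and 0.142, 0.11 and 0.223 in the translation efficiency fit).

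Simulations changed 100 genes at each size. The footprint test of muscle recovered 43 at 2-fold and 87 at 4-fold (2 of 16813 unchanged called). Its translation efficiency test recovered 60 and 93 (10 of 18309). Real muscle had far more calls, so these rates may not hold there. The age test from codon 350 on recovered 98 and 100 (10 of 1827), and that at 15 s 73 and 100 (8 of 5173). Alternatives included DESeq2 1.42.0, RLE size factors, no filter on low counts, only the 2 organs compared, the animal block, other levels, windows and minimums, and leaving out each library. The rest used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

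Footprint count libraries held 2027143 to 14043713 counts and mRNA libraries 17569322 to 30005751. Run-off libraries held 537880 to 8604589 footprint equivalents. Libraries carry no molecular identifiers, so floors and intervals cover counting error only. The coverage files do not tell reads of near-identical genes apart, and counts of the Mup, Serpina1, Serpina3, Ces, Cyp2c and Gst families are uncertain for the same reason. Genes are given by symbol, since the files give no coordinates.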

Results

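Ribosome footprints and mRNA were measured in organs of C57BL6 mice to ask whether ribosomes move at the same rate across organs and ages. Run-off libraries were made 15, 30, 45 and 60 s after harringtonine, which stops starting ribosomes. They came from young liver (12 libraries), young kidney (16), young skeletal muscle (11) and, up to 45 s, old liver (12). Each library came from 1 organ of 1 animal. Untreated footprints came from 9 organs (21 libraries, of which 4 of liver, 2 of kidney and 2 of muscle) and untreated mRNA from 8 organs (24 libraries, 3 per organ). Footprints after 5 or 30 min of harringtonine came from 8 organs (26 samples in 8 files). Untreated footprint libraries held 7673058 to 9805378 counts in liver, 11011050 and 11023327 in kidney, and 4564163 and 9133130 in muscle. mRNA libraries held 26736752 to 30005751 counts in liver, 24896621 to 27099345 in kidney and 25329877 to 27340370 in muscle. Run-off libraries held 565461 to 4799540 footprint equivalents in young liver, 537880 to 4657119 in kidney, 1892522 to 8604589 in muscle and 734266 to 4663404 in old liver.

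Footprints left the start of coding sequences progressively in all 4 groups, and from 30 s on the emptied stretch was longest in young liver and shortest in muscle. Positions are the codon at which the density, divided by that of untreated libraries, reached 0.5 of its downstream level. Young liver stood at codon 69.7 ± 19.4 (SD, n = 3) at 15 s, 178 ± 32.8 (n = 3) at 30 s, 278 ± 17.3 (n = 3) at 45 s and 337 ± 22.4 (n = 3) at 60 s. In kidney the position was 76.2 ± 16.7, 142 ± 13, 231 ± 25.1 and 296 ± 9.17 codons (SD, n = 4 per time). In muscle it was 31.5 ± 9.72 (n = 3), 82.3 ± 7.85 (n = 3), 157 ± 1.37 (n = 2) and 219 ± 6.42 codons (n = 3). Old liver stood at 46.0 ± 18.1, 129 ± 15 and 222 ± 18.2 codons (n = 4 per time), where animal 108 at 15 s lay at codon 20, the lowest searched. Without it the slope of divided positions in old liver was 5.60 ± 0.375 codons per s. In young liver at 30 s the library of animal 72 lay at codon 215, above the others at 166 and 152.

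**Figure D1:**
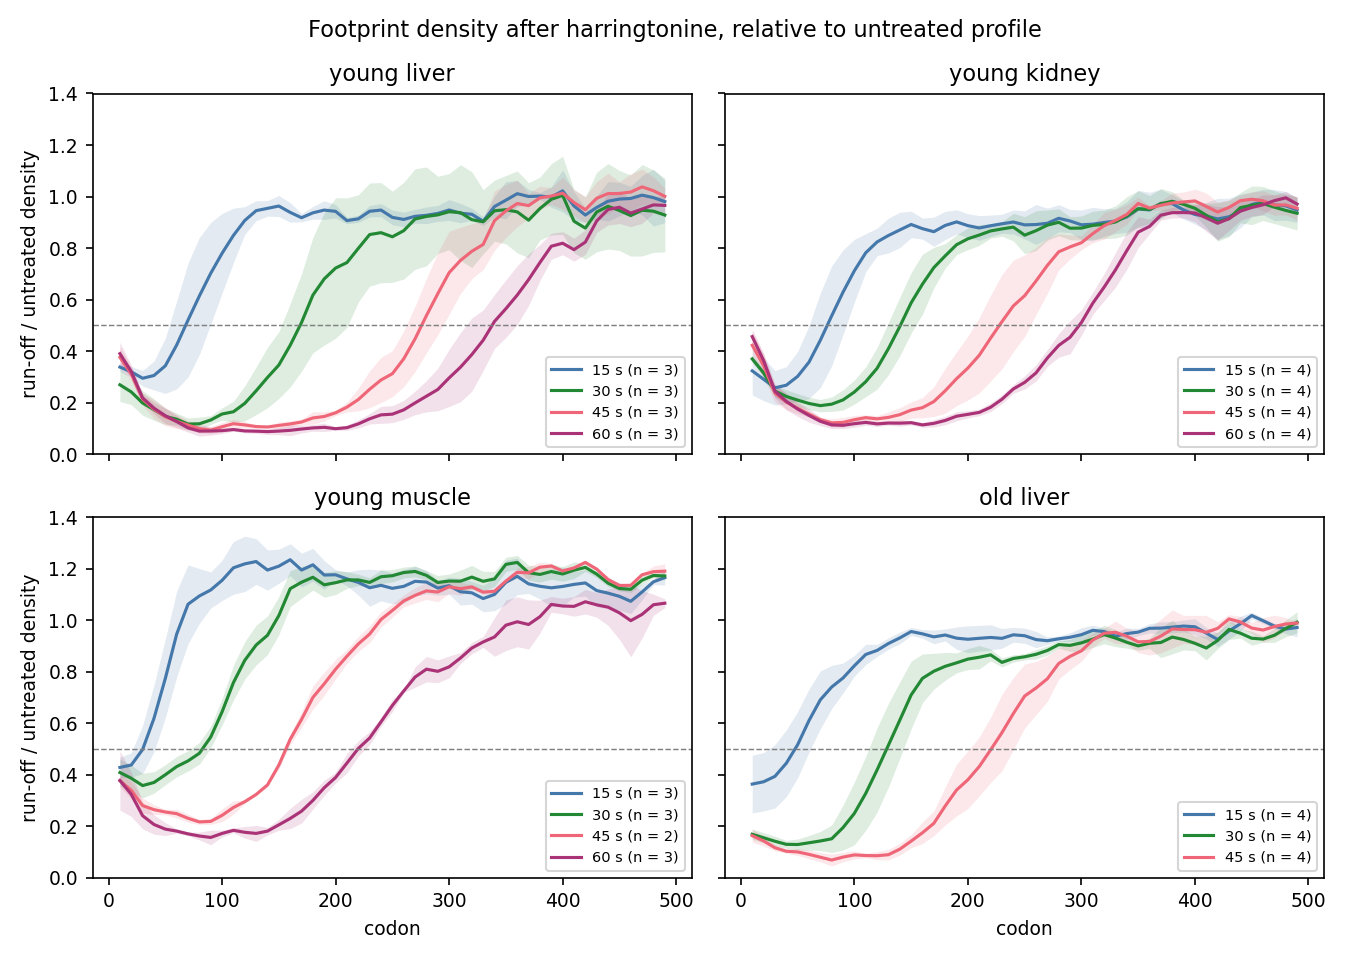
Density of run-off libraries divided by that of untreated libraries (y axis, ratio) against the codon (x axis, 10 to 490) for young liver, young kidney, young muscle and old liver. Lines are means of the libraries at 1 harringtonine time, bands their range, and the dashed line marks 0.5. The emptied stretch grew with time in each panel, and at 45 s the mean position reached codon 278 in young liver and 157 in muscle.

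The slope of the divided position on time gave a rate of 6.94 ± 0.612 codons per s (SE, n = 9 libraries at 15 to 45 s) in young liver, 5.15 ± 0.448 (n = 12) in kidney, 4.13 ± 0.297 (n = 8) in muscle and 5.86 ± 0.388 (n = 12) in old liver. The missing area, clipped at 0 after its signed form had been seen, gave 5.95 ± 0.706, 4.10 ± 0.412, 3.31 ± 0.358 and 5.13 ± 0.319 codons per s, so both measures put the 4 groups in the same order. Every slope differed from 0 by permutation of the times with either measure (p = 0.00119 in young liver and 0.00179 in muscle, the smallest that exact permutation can give there, 6e-05 in kidney and old liver). With the position rule chosen at the outset, without division, no slope of the 3 young organs differed from 0. With it 30 of the 41 libraries lay at codon 20, the lowest searched (8 of 9 in young liver, 11 of 12 in kidney, 7 of 8 in muscle and 4 of 12 in old liver). Its slopes were 0 ± 1.52 (p = 1, exact), -0.307 ± 0.244 (p = 0.665, permutation), 2.11 ± 1.33 (p = 0.25, exact) and 6.03 ± 0.363 codons per s (p = 6e-05, permutation). Undivided profiles searched from their lowest point on had no crossing in 13 of the 41 libraries.

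**Figure D2:**
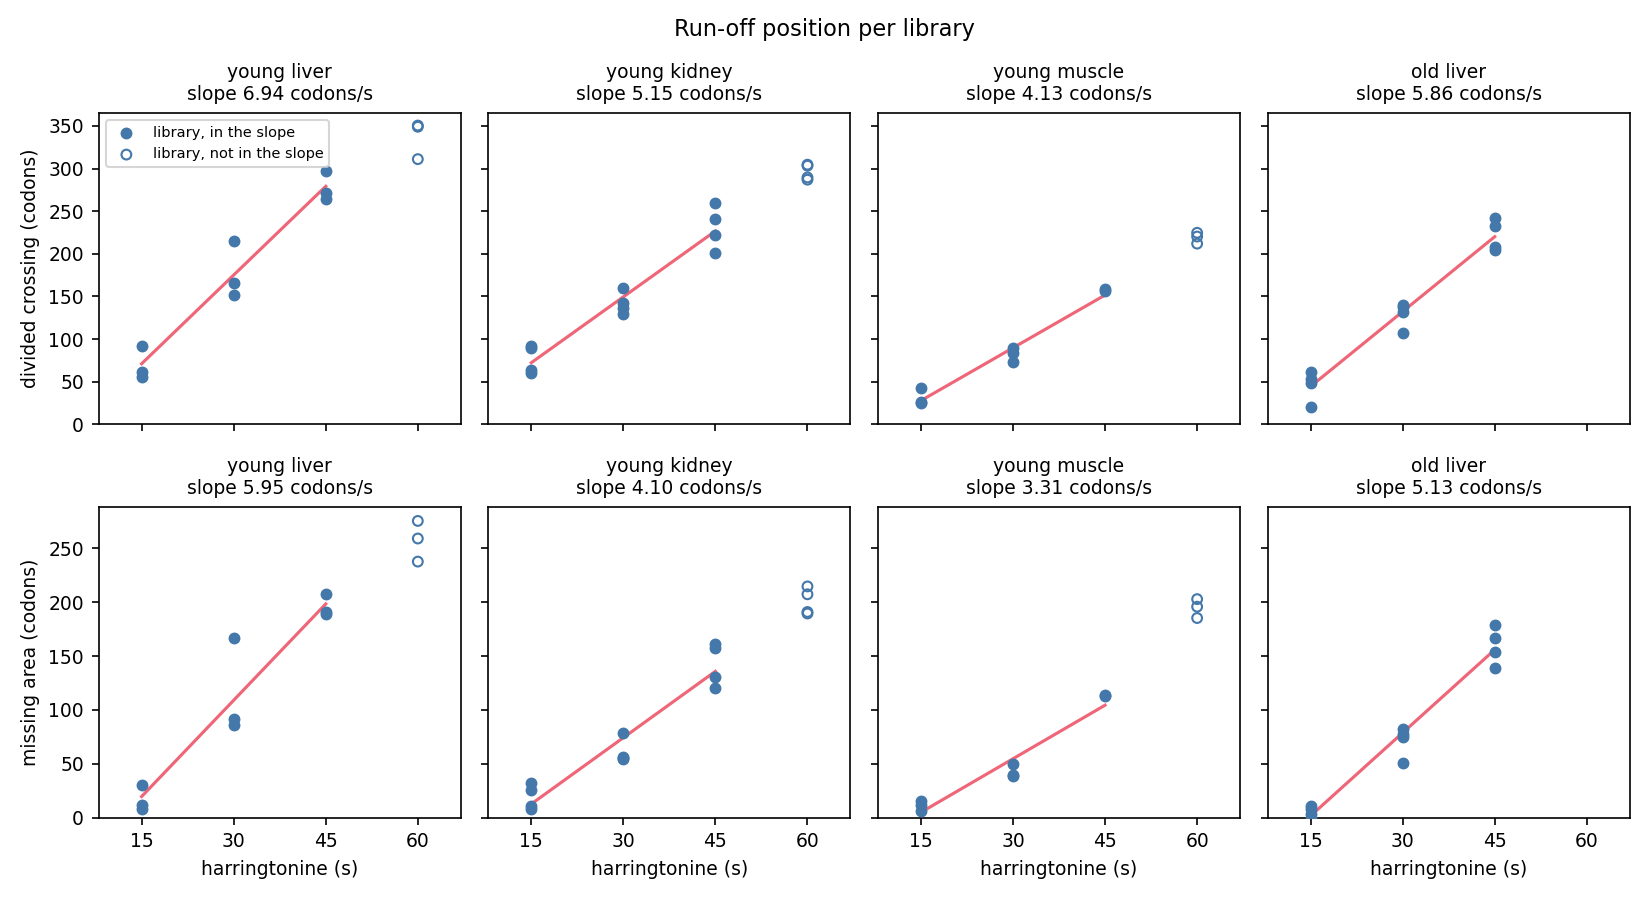
Run-off position in codons (y axis) of each library against harringtonine time in s (x axis) for the divided position (top) and the missing area (bottom) in young liver, young kidney, young muscle and old liver. Filled points (15 to 45 s) entered the slope drawn as a line, open points (60 s) did not. The slopes of the top panels are 6.94, 5.15, 4.13 and 5.86 codons per s.

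Over 15 to 45 s the rate of kidney lay below that of liver, and that of muscle below both. No organ difference passed the planned test with the divided position or the clipped area. The order of rates did not hold from 45 to 60 s. There the mean missing area grew from 195.5 to 257.2 codons in young liver, 142.3 to 200.5 in kidney and 113.5 to 194.5 in muscle. Mean divided positions grew from 278 to 337, from 231 to 296 and from 157 to 219 codons. The divided slope of kidney minus liver was -1.79 ± 0.758 codons per s (SE, 21 libraries; exact permutation of organ labels within times, p = 0.0433, adjusted p = 0.173). Muscle minus liver was -2.81 ± 0.68 (17 libraries; exact p = 0.202, adjusted p = 0.404) and muscle minus kidney -1.02 ± 0.537 (20 libraries; exact p = 0.475, adjusted p = 0.475). With the missing area the differences were -1.85 ± 0.818 (exact p = 0.0302, adjusted p = 0.101), -2.64 ± 0.792 (exact p = 0.0505, adjusted p = 0.101) and -0.790 ± 0.546 codons per s (exact p = 0.252, adjusted p = 0.252). With the signed area they were -2.25 (exact, adjusted p = 0.062), -3.86 (exact, adjusted p = 0.004) and -1.61 (exact, adjusted p = 0.0786), so muscle minus liver passed in that form. Without division they were -0.307 (exact, adjusted p = 1), 2.11 (exact, adjusted p = 0.533) and 2.42 codons per s (exact, adjusted p = 0.381), opposite in sign for muscle. When the mean position of each group was removed before permuting, so that a constant offset between organs no longer entered, muscle minus liver passed with both measures (exact, adjusted p = 0.009 divided and 0.01 by area) and kidney minus liver with the area (exact, adjusted p = 0.0212). Over other settings the divided differences ran from -1.90 to -1.02, from -2.99 to -1.77 and from -1.16 to -0.751 codons per s, and those by area from -2.25 to -1.18, from -3.86 to -1.18 and from -1.61 to -0.00440 (muscle minus kidney at 15 to 60 s, exact, adjusted p = 0.986). Labels were permuted without regard to animals that gave several organs. Among animals shared by 2 organs at 15 to 45 s, the divided position of muscle lay behind that of liver in 7 of 7 and behind kidney in 7 of 7, and that of kidney behind liver in 7 of 9. By area the counts were 6 of 7, 6 of 7 and 7 of 9. A position that lies behind at each time is not by itself a lower rate. Muscle was lysed by another protocol.

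Old liver ran off at 5.86 codons per s and young liver at 6.94, a difference of -1.08 ± 0.725 codons per s (SE, 21 libraries) that did not pass the test (exact permutation within times, p = 0.322, adjusted p = 0.43). The missing area gave -0.818 ± 0.775 (exact p = 0.221, adjusted p = 0.252). Over the alternatives of either measure old liver stayed below young liver, from -1.23 to -0.976 codons per s divided and from -0.909 to -0.460 by area, without passing. Undivided positions gave the opposite sign, 6.03 ± 1.56 (exact p = 0.0286, adjusted p = 0.114), with 8 of the 9 young libraries at codon 20. This difference passed when an old 45 s library was left out (5.95 codons per s without animal 107, 5.73 without 113, 6.20 without 120 and 6.23 without 125, exact, adjusted p = 0.04 each). Age cannot be told apart from the submission batch, since all old and no young libraries came with the larger gene set, and the untreated profile was that of young liver.

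No rate difference between transcripts of high and low footprint abundance passed the test. A constant offset of position between the classes widens the null of its sign flips, so this does not show equal rates. High minus low was -0.317 codons per s in young liver (229 transcripts in each class; exact sign flips, adjusted p = 0.25), 0.111 in kidney (431 each; exact, adjusted p = 0.75), 0.331 in muscle (633 each; exact, adjusted p = 0.62) and 0.375 in old liver (214 and 215; exact, adjusted p = 0.406) with the divided position. With the missing area the high class was ahead in each group, by 0.644 (exact, adjusted p = 0.328), 0.607 (0.328), 0.775 (0.312) and 0.455 codons per s (0.312). Without division the values were 0, -0.403, 4.64 and 0.6 codons per s (exact, adjusted p = 1, 1, 0.25 and 0.25). The divided value of kidney changed sign to -0.0607 without the 45 s library of animal 53.

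Long harringtonine gathered footprints at the start codon, as a share of coding footprints in codons 1 to 5, in 8 organs. After 5 min the share was 28.8% in kidney beside 1.7 ± 0.086% (SD, n = 2) untreated and 29% beside 3.52 ± 0.13% (n = 2) in heart. It was 40.2% beside 5.41 ± 0.18% (n = 2) in pancreas, 24.1% beside 2.23 ± 0.026% (n = 2) in lung and 21.9% beside 2.53 ± 0.15% (n = 2) in muscle. Liver reached 12.9% beside 2.78 ± 0.16% (n = 4). After 30 min testis held 21.1% beside 2.32 ± 0.08% (n = 2), and brain 4.48% (1 animal, 95% Wilson interval 4.45 to 4.51%) beside 2.1 ± 0.15% (n = 2), a ratio of 2.13 against 16.9 in kidney. The long harringtonine files pooled 3 or 4 animals except for brain, so these values have no replicate check and were not tested.

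In untreated footprints, kidney against liver asked which proteins each organ was translating, and transport proteins of the nephron stood against secreted and metabolic proteins of hepatocytes. All 28 measured proximal tubule genes were higher in kidney (28 adjusted over the list alone, median log2 fold change 10.56, 10.36 with genes at 0 set to their bound, camera adjusted p = 4.15e-13, adjusted p = 0.0838 with an estimated correlation). The sodium-coupled transporter Slc5a12 was at least 1227-fold higher (166 ± 13.4 CPM, SD, n = 2, against 0, n = 4) and Slc34a3 at least 382-fold. The endocytic receptor Cubn rose by 11.97 ± 0.81 (log2, SE) and Miox, which breaks down inositol, by 11.61 ± 0.94. All 28 distal nephron and collecting duct genes were higher as well (28 adjusted over the list alone, median 10.54, 8.49 at the bound with 10 members at 0 in liver, adjusted p = 1.3e-17, 0.00747 as adjusted p with an estimated correlation). Among them were the salt transporters Slc12a3 (13.18 ± 0.78) and Slc12a1 (12.42 ± 0.67), the tight junction gene Cldn10 (at least 1038-fold) and Hsd11b2 (at least 1027-fold), which inactivates corticosteroids. The 5 largest increases among abundant genes, here and below those with a mean log2 CPM of 5 or more over the libraries compared, were in Gpx3, a secreted glutathione peroxidase (10.14 ± 0.45; 7713 ± 269 against 6.74 ± 2.99 CPM), Lrp2, the partner of Cubn (10.00 ± 0.86; 6332 ± 440 against 6.06 ± 4.88 CPM), Acsm2 (9.37 ± 0.91), Ldhb (8.36 ± 0.28) and Cd63 (6.82 ± 0.17). Their adjusted p ran from 1.02e-14 to 1.03e-07. Liver held 5, 24, 1 and 3 counts of Cubn, Miox, Slc12a3 and Slc12a1, all but 1 of them in the library of animal 27. Without it Cubn, Slc12a3 and Slc12a1 were at least 5028-fold, 2866-fold and 4292-fold higher, Miox was at 15.36 and Lrp2 at 10.71.

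Of 33 measured secreted hepatocyte proteins 33 were lower in kidney (33 adjusted over the list alone, median -9.45, camera adjusted p = 1.21e-19, adjusted p = 0.0838 with an estimated correlation). Haemopexin Hpx fell from 11720 ± 4125 to 5.69 ± 2.34 CPM (-11.00 ± 1.48), followed by Serpina3k (-10.99), Ahsg (-10.96) and Itih4 (-10.79). The urea cycle had 7 of 8 genes lower (7 adjusted over the list alone, median -5.26, adjusted p = 6.68e-06, adjusted p = 0.0548 with an estimated correlation). Its entry enzyme Cps1 stood at 7.87 ± 5.31 against 11359 ± 891 CPM (-10.49 ± 1.00), next to Arg1 (-10.30), Otc (-10.27) and Nags (-8.80). Cholesterol synthesis had 19 of 22 lower and 1 higher (20 and 1 adjusted over the list alone, median -2.43, adjusted p = 7.6e-10, adjusted p = 0.0838 with an estimated correlation). Fdps (-4.52 ± 0.35), Msmo1 (-4.24) and Sc5d (-4.19) were among the lowest. ER chaperones and translocation factors had 25 of 30 lower (25 adjusted over the list alone, median -1.11, adjusted p = 5.17e-12, adjusted p = 0.0731 with an estimated correlation). Sdf2l1 (-2.35 ± 0.31), Pdia4 (-1.86), Manf (-1.80) and Sec63 (-1.76) led them. Markers of macrophages and Kupffer cells moved with them, 16 of 16 lower (16 adjusted over the list alone, median -2.22, adjusted p = 1.96e-11, adjusted p = 0.0548 with an estimated correlation). Vsig4 was at least 303-fold lower, and Clec4f (-10.74 ± 0.50; 0.108 against 209 ± 21.5 CPM), Cd5l (-8.76) and Marco (-8.09) fell too. Low kidney counts make some folds depend on 1 library. Without kidney footprints of animal 27 Serpina3k was at -11.66, Cps1 at -11.42, Arg1 at -11.19, Otc at -12.43, Marco at -7.28 and Nags at least 393-fold lower. Without those of animal 26 Otc was at -9.45, Nags at -7.87, Cd5l at -9.56 and Marco at least 64.5-fold lower (-7.42 without the liver library of animal 26). Smooth muscle markers were higher in 10 of 10 (10 adjusted over the list alone, median 2.75, adjusted p = 0.00552, adjusted p = 0.37 with an estimated correlation).

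The largest decreases among abundant genes of kidney were in Cyp2c70 (-11.90 ± 0.76), Cfhr2 (-11.86), Asgr2 (-11.52), Ces3b (-11.50) and Mup17 (-11.46). Cyp2c70, Ces3b and Mup17 belong to families whose counts are uncertain. Cfhr2 was at -12.71 and Ces3b at -12.64 without the kidney library of animal 27, and Ces3b at -10.87 without that of animal 26. In all, 7575 of 18047 genes passed in edgeR's quasi-likelihood test (4583 higher, 2992 lower), on a scale where the median gene stood at 0.12 (0.04 with RLE size factors). Elongation factors did not pass: Eef1a1 0.16 ± 0.26 (adjusted p = 0.695), Eef1a2 -0.45 ± 0.89 (0.76), Eef2 0.35 ± 0.20 (0.195) and Eif5a -0.46 ± 0.21 (0.0942). Eif5a passed with RLE size factors (-0.54, adjusted p = 0.0457), with only the 2 organs in the fit (-0.55, 0.00395) and in DESeq2 (-0.54, 0.00897).

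**Figure D3:**
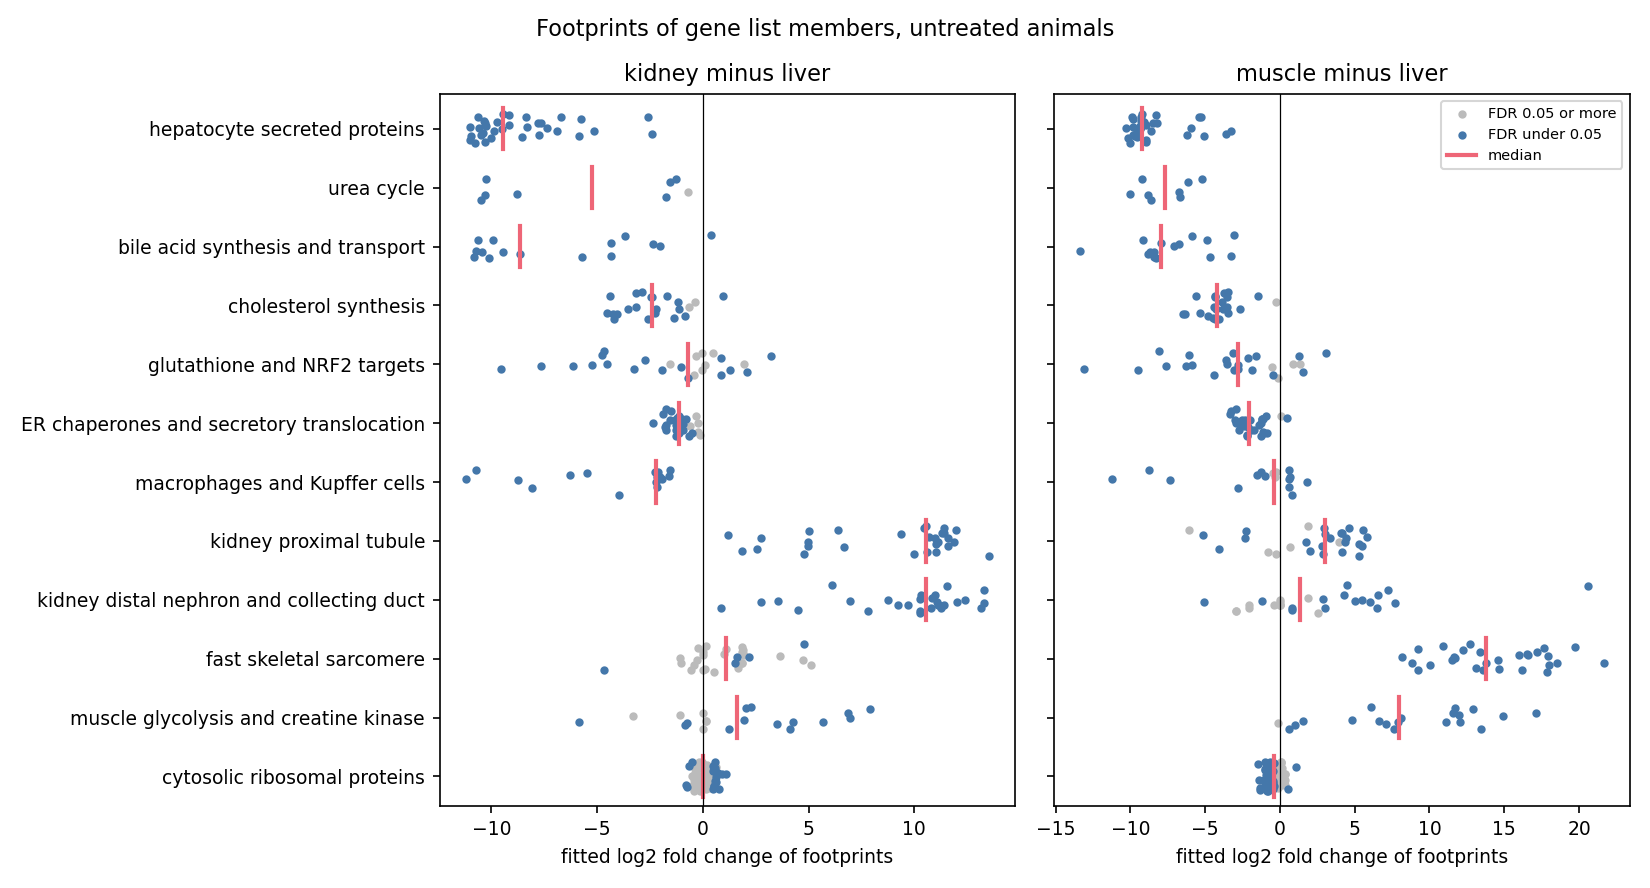
Log2 fold changes of footprints (x axis) of the members of 12 gene lists (y axis) in kidney against liver and muscle against liver, fitted by edgeR. Each point is a gene, blue points passed the false discovery rate of 0.05, and the red line is the list's median. Proximal tubule genes had a median of 10.56 in kidney, and fast sarcomere genes 13.76 in muscle.

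Muscle footprints were higher than those of liver in all 29 fast sarcomere genes (29 adjusted over the list alone, median 13.76, 13.08 with 9 members at 0 in liver set to their bound, camera adjusted p = 1.08e-16, adjusted p = 0.0857 with an estimated correlation). The fast myosin heavy chains Myh4 and Myh1 were at least 334812-fold (45369 ± 13552 CPM, SD, n = 2, against 0, n = 4) and 37784-fold higher, troponin C Tnnc2 at least 88671-fold and Actn3 at least 26359-fold. Glycolysis and creatine kinase genes were higher in 19 of 20 (19 adjusted over the list alone, median 7.99, adjusted p = 7.07e-14, 0.0106 as adjusted p with an estimated correlation). The AMP deaminase Ampd1 was at least 14754-fold higher, creatine kinase Ckm by 14.92 ± 1.03 (25900 ± 3092 against 0.848 CPM), Phkg1 by 13.45 (at least 3584-fold without the liver library of animal 29) and Pgam2 by 12.94 (13.67 without that of animal 27). The 5 largest increases taken by the naming rule were in Eno3 (11.96 ± 0.44), glycogen phosphorylase Pygm (11.72), nebulin Neb (9.22), Tpm2 (9.22) and Tpm1 (8.80 ± 0.42). Eef1a2, the muscle and neuron form of elongation factor 1A, stood at 1938 ± 298 against 0.446 CPM (12.03 ± 0.53, adjusted p = 2.5e-12). Eef1a1 was lower (855 against 2186 CPM; -1.35 ± 0.28, adjusted p = 0.00042), Eif5a was lower (-0.91 ± 0.22, 0.00179) and Eef2 was -0.04 ± 0.21 (adjusted p = 1; positive, 0.07 to 0.09, under 3 other settings).

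Cholesterol synthesis was lower in muscle in 21 of 22 genes (21 adjusted over the list alone, median -4.18, adjusted p = 1.04e-10, adjusted p = 0.0857 with an estimated correlation). Tm7sf2 (-6.49 ± 0.62), Msmo1 (-6.34) and Idi1 (-5.33) had low values. Glutathione and NRF2 target genes were lower in 18 of 25 and higher in 3 (the same counts, 18 and 3, adjusted over the list alone, median -2.83, adjusted p = 6.04e-06, adjusted p = 0.0619 with an estimated correlation). The glutathione transferases Gstm3 and Gsta2 were at least 580-fold and 48.7-fold lower, Gsta3 by -8.07 ± 0.51, and Gsta1 at least 13.3-fold (adjusted p = 0.0642 in DESeq2). Ribosomal protein genes were lower in 36 of 79 and higher in 2 (36 and 2 adjusted over the list alone, median -0.40, adjusted p = 0.00102, adjusted p = 0.573 with an estimated correlation). Rpl35a (-1.46 ± 0.22), Rpl18 (-1.41), Rpl29 (-1.35) and Rps6 (-1.35) fell most. The largest decreases among abundant genes were in Apoc4 (at least 4780-fold lower), Cyp2c44 (at least 3445-fold), Cyp2a12 (-12.33), complement factor Cfi (-11.94) and coagulation factor F12 (-11.83). Without the muscle library of animal 26 Cyp2a12 was at -10.84, Cfi at -11.05, Gsta3 at -9.71, Tm7sf2 at -5.03 and F12 at least 1221-fold lower. Without that of animal 27 Cfi was at -12.65, F12 at -11.24 and Gsta3 at -7.36, and Cyp2a12 and Tm7sf2 were at least 1414-fold and 473-fold lower. Over all genes, 9472 of 18047 passed in edgeR (4837 higher, 4635 lower). Markers of other cells moved with muscle, fibroblast genes being higher in 16 of 19 and lower in 2 (16 and 2 adjusted over the list alone, median 4.69, adjusted p = 4.77e-07, adjusted p = 0.16 with an estimated correlation).

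Kidney genes stood high in 1 of the 2 muscle footprint libraries. Proximal tubule genes were higher in 18 of 28 and lower in 4 (18 and 5 adjusted over the list alone, median 3.01, 2.90 at the bound, camera adjusted p = 0.0827, adjusted p = 0.691 with an estimated correlation). Without the muscle library of animal 26, 4 were higher and 4 lower (median -0.57, adjusted p = 1). Car4 stood at 5.33 ± 3.88 CPM against 0.0784 (5.80 ± 0.91, adjusted p = 4.19e-05; 4.67 without animal 26). Without animal 26 the calls of Cubn (5.55; without it 1.50, adjusted p = 0.497), Kap (5.46; without it 2.28, 0.303) and Slc5a12 (at least 2.98-fold; without it 0.00, adjusted p = 1) ended, and Slc5a12 also did not pass with the animal as a block (adjusted p = 0.0858). Without the muscle library of animal 27 Cubn was at 6.42, Kap at 6.43 and Slc5a12 at least 5.96-fold higher. Without the liver library of animal 27 Car4 and Cubn were at least 28-fold and 53.4-fold higher and Kap was at 11.40.

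mRNA of kidney against liver was higher for nephron genes and lower for genes of protein synthesis and breakdown. The largest increases among abundant genes were in the nephron genes Mep1a (10.04 ± 0.29; 1456 ± 114 CPM, SD, n = 3, against 1.38 ± 0.21, n = 3), Fxyd2 (9.76), Slc22a12 (9.75), Slc34a1 (9.73) and Slc12a1 (9.71), which in liver stood at 0.0947 to 0.119% of their kidney level, beside lower quartiles of 0.122 and 0.127% for proximal tubule and distal nephron genes. The lowest were the urinary protein genes Mup15 (-11.06 ± 1.13; -10.29 without the liver library of animal 26), Mup2 (-10.97), Mup19 (-10.96) and Mup14 (-10.93), whose counts are uncertain between copies, and Mug1 (-10.98), at 0.0468 to 0.0513% of their liver level. Folds near such shared levels do not rank these genes. Proteasome genes were lower in 30 of 31 (30 adjusted over the list alone, median -0.61, camera adjusted p = 4.09e-08, adjusted p = 0.283 with an estimated correlation). Psmd11 (-1.13 ± 0.07), Psmb2 (-0.90), Psmd4 (-0.90) and Psma5 (-0.87) fell most. Ribosomal protein genes were lower in 65 of 79 (67 adjusted over the list alone, median -0.41, adjusted p = 1.47e-08, adjusted p = 0.441 with an estimated correlation). Rpl12 (-0.92 ± 0.08), Rps18 (-0.87), Rpl13a (-0.84) and Rps26 (-0.82) were the lowest of them. Aminoacyl-tRNA synthetases, which charge tRNAs, were lower in 16 of 22 and higher in 2 (16 and 2 adjusted over the list alone, median -0.42, adjusted p = 0.000458, adjusted p = 0.441 with an estimated correlation). Tars fell from 150 to 33.8 CPM (-2.15 ± 0.09), ahead of Aars (-1.93), Cars (-1.78) and Mars (-1.25). Eef1a1 (-0.73 ± 0.18), Eef2 (-0.53 ± 0.12) and Eif5a (-0.51 ± 0.08) were lower with adjusted p of 0.00123, 0.000631 and 1.37e-05, and Eef1a2 was -0.47 ± 0.32 (adjusted p = 0.23). In all 11609 of 19161 genes passed in edgeR (6586 higher, 5023 lower), 6736 of them by at least 2-fold. Macrophage and Kupffer cell markers were lower in 16 of 16 here too (16 adjusted over the list alone, median -2.78, adjusted p = 1.42e-08, adjusted p = 0.196 with an estimated correlation).

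mRNA of muscle against liver was higher for contraction and respiration. The largest increases among abundant genes were in Tcap (10.29 ± 0.31; 2513 ± 204 CPM, SD, n = 3, against 2.00 ± 0.342, n = 3), skeletal actin Acta1 (10.24), Tnnc2 (10.22), Eef1a2 (10.20 ± 0.35) and Ampd1 (10.17). Eef1a2 mRNA stood at 1992 ± 93.3 against 1.68 CPM. In liver mRNA, the 29 fast sarcomere genes with 100 CPM or more in muscle stood at a median of 0.0956% of their muscle level (quartiles 0.0915 and 0.106%), and these 5 at 0.0797 to 0.0865%. The lowest were Mup15 (-10.65; -9.88 without the liver library of animal 26), Rdh7 (-10.64), Apoa5 (-10.64), plasminogen Plg (-10.62) and Pzp (-10.59), at 0.062 to 0.0649% of their liver level. The order of genes near such levels is not a ranking. Nuclear-encoded respiratory chain genes were higher in 34 of 36 (34 adjusted over the list alone, median 0.79, camera adjusted p = 9.54e-07, adjusted p = 0.42 with an estimated correlation). Cytochrome c Cycs (1.89 ± 0.15), Ndufv2 (1.59), Ndufs4 (1.45) and Cox5a (1.44) rose most. Synthetases went both ways, 12 of 22 higher and 6 lower (12 and 6 adjusted over the list alone, median 0.35, adjusted p = 0.395). Aimp2, a scaffold of the synthetase complex, was at 4.05 ± 0.11 (209 ± 31.9 against 12.6 CPM) and Aimp1 at 1.34, while Tars (-1.40) and Aars (-1.35) were lower. Initiation factors did too, 16 of 38 higher and 12 lower (16 and 12 adjusted over the list alone), with a positive median of 0.12 and a camera direction of down (adjusted p = 0.999). Eif1a (-1.65 ± 0.13), Eif4a1 (-1.41) and Pabpc1 (-1.24) were lower and the cap-binding Eif4e (1.15 ± 0.12) higher. Eef1a1 was lower by -2.61 ± 0.19, Eef2 by -0.72 ± 0.12 and Eif5a by -0.30 ± 0.08 (adjusted p = 3.59e-11, 1.85e-05 and 0.00273). In all 12805 of 19161 genes passed (6912 higher, 5893 lower). Fibroblast markers were higher in 16 of 19 and lower in 3 (16 and 3 adjusted over the list alone, median 3.54, adjusted p = 9.74e-05, adjusted p = 0.406 with an estimated correlation).

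Translation efficiency, the footprints of a gene relative to its mRNA, was higher in kidney than in liver for 30 of 79 ribosomal protein genes (40 adjusted over the list alone, median 0.53, camera adjusted p = 1.2e-28, adjusted p = 0.3 with an estimated correlation). Rplp0 (1.42 ± 0.19) held 156 against 75.3 footprint CPM and 416 against 536 mRNA CPM. Next were Rplp1 (1.41 ± 0.17), Rps2 (1.39 ± 0.19) and Rps12 (1.35 ± 0.32; without the kidney footprint library of animal 27, adjusted p = 0.0814). Of 22 synthetases 2 were lower (4 adjusted over the list alone, median -0.17, adjusted p = 4.79e-05, adjusted p = 0.764 with an estimated correlation). They were Lars (-0.84 ± 0.15, adjusted p = 0.00068) and Farsb (-0.71 ± 0.20, 0.0319). Of 17 elongation factors 3 were higher (3 adjusted over the list alone, median 0.19, adjusted p = 0.0959). These were Eef2 (0.93 ± 0.21, adjusted p = 0.00636), Eef1a1 (0.94 ± 0.27, 0.036) and Eef1b2 (0.51 ± 0.14, 0.0318), the last 2 not with RLE size factors (adjusted p = 0.0881 and 0.138). Eef1a2 (0.06 ± 1.03) and Eif5a (0.10 ± 0.21) did not pass (adjusted p = 1 each) and were negative with RLE size factors (-0.07 and -0.02).

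Gpld1, a secreted phospholipase, had the lowest kidney-minus-liver difference in translation efficiency among abundant called genes (-4.59 ± 0.26, adjusted p = 1.14e-13), with 1.81 against 462 footprint CPM and 33.4 against 353 mRNA CPM. It was followed by Akr1d1, a bile acid enzyme (-1.76 ± 0.29), amylase Amy1 (-1.67 ± 0.50), Acsl5 (-1.46 ± 0.28) and Arhgef10l (-1.44 ± 0.26). The highest among abundant genes were Ankrd13c (2.60 ± 0.27, adjusted p = 1.05e-07), the receptor Lrp1 (1.93 ± 0.30), fibronectin Fn1 (1.92 ± 0.57), Igfbp5 (1.78 ± 0.51) and Irf2bp2 (1.77 ± 0.31). In all 879 of 19612 genes passed in edgeR (757 higher and 122 lower, 86.1% higher), on a scale where the median gene stood at 0.10. With RLE size factors, where it stood at 0.00, 641 passed (438 and 203, 68.3% higher), and in DESeq2 1493 (846 and 647, 56.7% higher). Without the kidney footprint library of animal 26 or 27 the count was 491 (450 and 41) or 403 (357 and 46), and without the liver footprints of animal 27 217 were lower. The calls of Fn1, Igfbp5, Eef1a1 and Eef1b2 ended without the kidney footprints of animal 26 (adjusted p = 0.192, 0.123, 0.143 and 0.128), those of Amy1 and Farsb without animal 27 (0.515 at -0.84, and 0.209). Amy1 was at -3.76 without animal 26. Each ended without other libraries too, in 11, 10, 9, 8, 9 and 8 of the 12 omissions, in that order. With the animal as a block Igfbp5 (adjusted p = 0.076), Fn1 (0.083), Amy1 (0.0537), Farsb (0.0576), Eef1a1 (0.0984) and Eef1b2 (0.0609) did not pass either. With RLE size factors the calls of Igfbp5 (1.65, adjusted p = 0.074), Fn1 (1.80, 0.0788), Eef1a1 (0.82, 0.0881) and Eef1b2 (0.39, 0.138) ended. With only the 2 organs in the fit those of Eef1b2 (0.42, 0.105) and Amy1 (-1.76, 0.0841) ended, and without a filter on low counts that of Amy1 (0.0515).

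**Figure D4:**
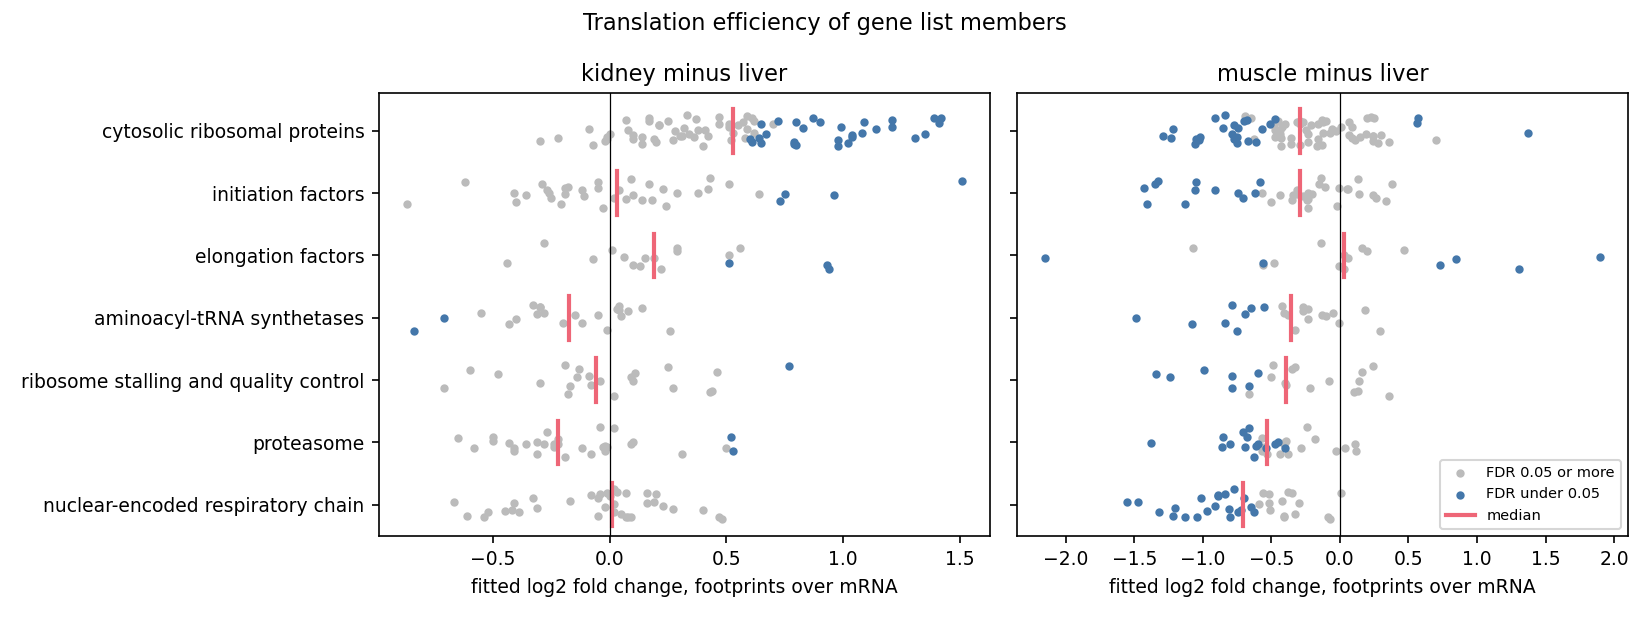
Log2 differences in translation efficiency (x axis) of the members of 7 gene lists (y axis) in kidney against liver and muscle against liver, fitted by edgeR. Each point is a gene, blue points passed the false discovery rate of 0.05, and the red line is the list's median. Ribosomal protein genes had a median of 0.53 in kidney and -0.29 in muscle, and respiratory chain genes -0.71 in muscle.

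In muscle, translation efficiency was lower than in liver for 22 of 36 respiratory chain genes (27 adjusted over the list alone, median -0.71, camera adjusted p = 1.7e-15, adjusted p = 0.271 with an estimated correlation). Ndufa4 (-1.55 ± 0.45), Atp5g1 (-1.47 ± 0.30), Cycs (-1.32 ± 0.26) and Ndufs4 (-1.22 ± 0.19) fell most. Ndufa4 did not pass without the muscle footprints of animal 27 (adjusted p = 0.0682). Proteasome genes were lower in 15 of 31 (20 adjusted over the list alone, median -0.53, adjusted p = 6.77e-08, adjusted p = 0.397 with an estimated correlation). Psma3 (-1.38 ± 0.21), Psmb7 (-0.86), Psmc6 (-0.85) and Psma7 (-0.80) were the lowest. Without muscle footprints of animal 26 or 27 Psma7 did not pass (adjusted p = 0.0521 or 0.068). Initiation factors were lower in 12 of 38 (13 adjusted over the list alone, median -0.29, adjusted p = 2.23e-05, adjusted p = 0.351 with an estimated correlation). Eif5b (-1.43 ± 0.17), Eif2s2 (-1.41), Eif4e (-1.35) and Eif4ebp2 (-1.33) led them. Genes of ribosome stalling and quality control were lower in 7 of 22 (9 adjusted over the list alone, median -0.40, adjusted p = 0.000629, adjusted p = 0.28 with an estimated correlation). Eif4e2 (-1.24 ± 0.21) and Nemf (-0.99) were lower, as were Ankzf1 (-1.34; -0.30 and adjusted p = 0.594 without the muscle footprints of animal 26, -2.77 without those of animal 27, and adjusted p = 0.0706 with only the 2 organs in the fit) and Abce1 (-0.79; adjusted p = 0.0671 without those of animal 27). Ribosomal protein genes were lower in 23 of 79 and higher in 3 (26 and 4 adjusted over the list alone, median -0.29, adjusted p = 2.76e-05, adjusted p = 0.596 with an estimated correlation). Rpl29 (-1.29 ± 0.25), Rpl35a (-1.23) and Rpl39 (-1.22) were lower and Rpl3 (1.37 ± 0.21) was higher. Without the muscle footprints of animal 26 these lists had 20, 12, 11, 5 and 18 lower members.

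Elongation factors went both ways in muscle, 4 of 17 higher and 2 lower (4 and 3 adjusted over the list alone, median 0.03, adjusted p = 0.92), and 3 higher and 4 lower without the muscle footprints of animal 26 (3 and 5 adjusted over the list alone, median -0.05). Dph3, needed for the diphthamide of elongation factor 2, was lower (-2.15 ± 0.22, adjusted p = 1.44e-08). Eef1a1 (1.31 ± 0.27, 0.000494), Eef2 (0.73 ± 0.21, 0.0113), Eef1a2 (1.90 ± 0.65, 0.0326) and Dph2 (0.85 ± 0.28, 0.0266) were higher. The Eef1a2 and Dph2 calls each ended in 4 of 12 omissions, with adjusted p up to 0.0994 (liver mRNA of animal 28) and 0.169 (muscle footprints of animal 26). Eif5a was -0.56 ± 0.21 (adjusted p = 0.0509) and passed with RLE size factors (-0.55, 0.0426), with only the 2 organs in the fit (-0.51, 0.0269), in DESeq2 (-0.55, 0.00398) and without the muscle mRNA of animal 27 (0.0481). The largest increases among abundant genes were in Myh4 (at least 320-fold), Pvalb (at least 150-fold), Tnnc2 (at least 76.9-fold), the calcium pump Atp2a1 (9.41 ± 0.96; at least 181-fold without the liver footprints of animal 27) and Myl1 (8.09 ± 1.19; at least 78.2-fold without those of animal 28). Liver mRNA held these at 0.0845 to 0.0933% of their muscle level and Eef1a2 at 0.0852% (1.56 CPM), near the 0.0956% median of fast sarcomere genes, while liver footprints held 0 or nearly 0. The source of those liver mRNA reads was not tested, so efficiencies of muscle-specific genes, these 6 included, are not read as changed. The lowest were Cyp2c44 (at least 14.3-fold lower), Gpld1 (-3.77 ± 0.27), Pon1 (-3.49 ± 0.79), Abcb4 (-3.46 ± 0.30) and the RNA-binding Ybx1 (-2.76 ± 0.17, adjusted p = 3.89e-13). Ybx1 held 82.7 against 284 footprint CPM and 571 against 289 mRNA CPM. edgeR called 4471 of 19612 genes (2399 higher, muscle genes included, 2072 lower). Markers of fibroblasts (12 of 19 higher, 12 adjusted over the list alone, median 1.19, adjusted p = 9.45e-05) and of macrophages (8 of 16, 8 adjusted over the list alone, median 1.18, adjusted p = 0.000331) moved with muscle (adjusted p = 0.425 each with an estimated correlation). Proximal tubule genes were higher in 18 of 28 (19 adjusted over the list alone, median 4.05, 3.29 at the bound, adjusted p = 3.1e-06, adjusted p = 0.425 with an estimated correlation) and in 2 without the muscle footprints of animal 26 (median 0.21). There Kap (5.60 with that library, 2.37 without, adjusted p = 0.416), Amn (5.55 and -2.65, adjusted p = 1), Slc13a1 (5.43 and -4.20, adjusted p = 0.775) and Slc7a9 (at least 18.1-fold, from 3 muscle and 1 liver footprints, and 1.71, adjusted p = 1) no longer passed, the last 3 with 0 muscle footprints left, nor did Kap in DESeq2 (adjusted p = 0.068). Without the liver footprints of animal 27 Kap was at 11.58 and Slc13a1 at least 17.2-fold higher, and without those of animal 26 Amn was at 6.72. Without the muscle footprints of animal 27 Kap, Amn and Slc13a1 were at 6.52, 6.17 and 6.13 and Slc7a9 at least 36.3-fold higher.

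Old liver carried more footprints on genes of fat synthesis than young liver and fewer on ER chaperones, counted from codon 350 on, where the divided density was 0.796 to 1.07 in young and 0.875 to 0.977 in old libraries. Of 9 measured genes of fatty acid and triglyceride synthesis 6 were higher (8 adjusted over the list alone, median 0.60, camera adjusted p = 2.25e-05, adjusted p = 0.224 with an estimated correlation). Fatty acid synthase Fasn stood at 10831 ± 3229 CPM (SD, n = 12) against 4356 ± 1568 (n = 9), a rise of 1.32 ± 0.20 (log2, SE; limma, adjusted p = 5.03e-05). The other members included malic enzyme Me1 (1.04 ± 0.22), Srebf1, a transcription factor of lipid synthesis (0.72 ± 0.18), and Lpin2 (0.67 ± 0.18). Cholesterol synthesis had 3 of 9 higher and 1 lower (4 and 1 adjusted over the list alone, median 0.33, adjusted p = 0.0364, adjusted p = 0.556 with an estimated correlation). Hmgcs1 (0.63 ± 0.21) and Srebf2 (0.45 ± 0.13) were higher and Cyp51 (-0.53 ± 0.17) was lower. Of 7 ER chaperone and translocation genes 5 were lower (6 adjusted over the list alone, median -0.52, adjusted p = 1.94e-05, adjusted p = 0.217 with an estimated correlation). They included the oxygen-regulated chaperone Hyou1 (-1.10 ± 0.20), Sec63 (-0.78 ± 0.13) and Rpn1 (-0.52 ± 0.09). The disulfide isomerase P4hb stood at 3055 ± 498 against 5817 ± 844 CPM (-0.93 ± 0.10, adjusted p = 2.01e-07). Of 18 secreted hepatocyte proteins 7 were lower and 1 higher (7 and 1 adjusted over the list alone, median -0.30, adjusted p = 0.00233, adjusted p = 0.287 with an estimated correlation). Itih3 (-0.75 ± 0.16), transferrin Trf (-0.57 ± 0.16), fibrinogen Fga (-0.53 ± 0.18) and complement factor Cfb (-0.51 ± 0.09) fell most. Of 5 male-biased liver genes 3 were lower (3 adjusted over the list alone, median -0.87, adjusted p = 0.00233, adjusted p = 0.217 with an estimated correlation). They were Ddx3y (-0.95 ± 0.15; its coding length differs between the gene sets), Slco1a1 (-0.87 ± 0.21) and C6 (-0.76 ± 0.15).

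**Figure D5:**
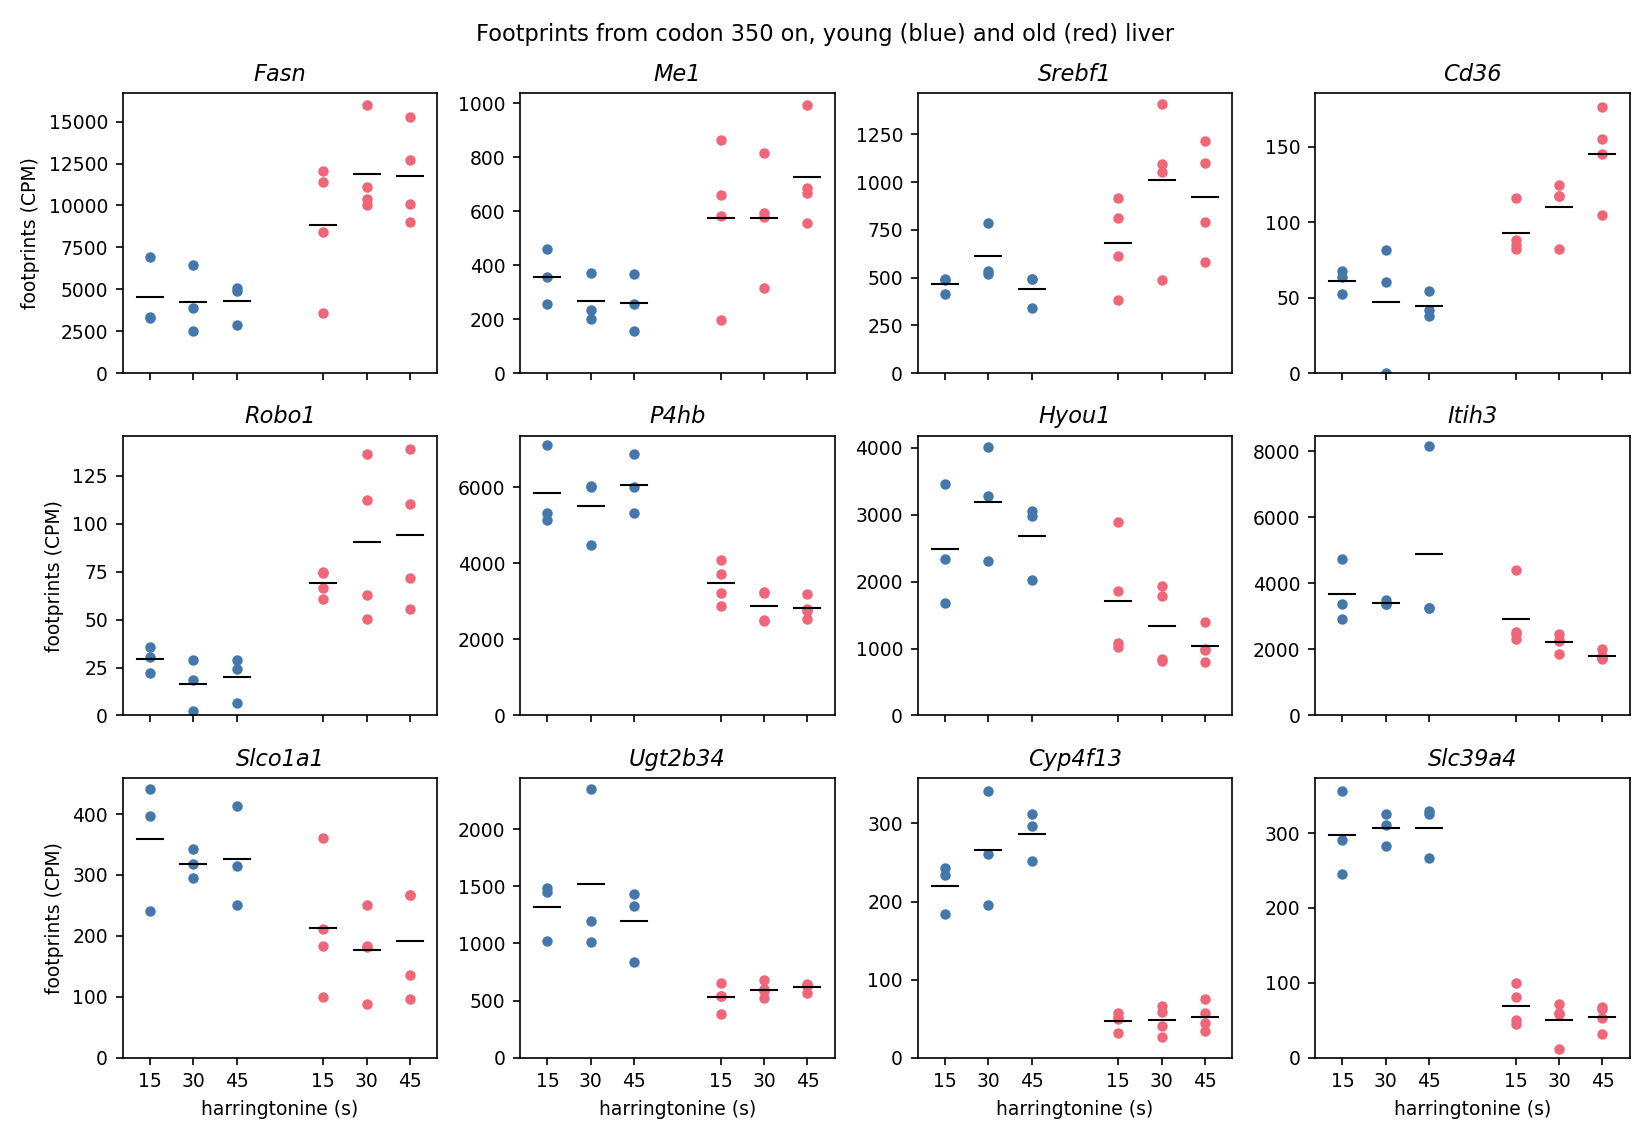
Footprint CPM from codon 350 on (y axis) of 12 genes in each library at 15, 30 and 45 s (x axis), young liver in blue and old liver in red. Black lines are the means at each time. Fasn averaged 10831 CPM in old and 4356 in young liver, and P4hb 3055 and 5817.

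The largest increases in old liver among abundant genes, every old library above every young one, were in Mia2 (4.23 ± 0.14; its coding length differs), the guidance receptor Robo1 (1.90 ± 0.28; 84.6 ± 31.4 against 22 ± 11.2 CPM), the fatty acid receptor Cd36 (1.41 ± 0.34), Dctn1 (1.19 ± 0.18) and Mib1 (1.15 ± 0.14). The lowest were the zinc transporter Slc39a4 (-2.43 ± 0.21; 58.0 ± 22.5 against 304 ± 34.9 CPM, adjusted p = 1.64e-09), Cyp4f13 (-2.32 ± 0.16), Ugt2b34 (-1.16 ± 0.14), Masp1 (-1.08 ± 0.12; its coding length differs) and P4hb. Eef1a1 was -0.23 ± 0.15 (adjusted p = 0.306), and the other 3 elongation factors were not measured here. In all 313 of 2045 genes passed in limma (148 higher, 165 lower), 35 of them by at least 2-fold. From codon 500 on 169 passed, and within single times 25 at 15 s, 7 at 30 s and 103 at 45 s. Fasn at 15 s alone was 0.91 (adjusted p = 0.356) and P4hb -0.76 (adjusted p = 0.106). Further changes shrank more there, to 0.56 for Cd36, 0.52 for Me1, 0.46 for Srebf1 and 0.01 for Lpin2, and to -0.62 for Hyou1, -0.20 for Sec63, -0.31 for Rpn1, -0.01 for Cyp51, -0.36 for Itih3 and -0.27 for Fga (adjusted p = 0.343 or more). At 30 s alone Trf was -0.14, Srebf2 0.28 and Cd36 2.00 (adjusted p = 0.776, 0.68 and 0.22). Of the genes named as changed from codon 350 on, only Mia2, Robo1, Slc39a4, Cyp4f13, Ugt2b34, Masp1 and Ddx3y passed at 15 s alone and only Mia2, Slc39a4, Cyp4f13, P4hb and Fasn at 30 s alone. At 45 s alone Hmgcs1, Srebf2, Fga and Slco1a1 did not pass. From codon 500 on Trf (-0.21, adjusted p = 0.458) and Fga (-0.33, 0.407) did not pass. Without a filter on low counts Hmgcs1 (adjusted p = 0.0996), Cyp51 (0.0665), Trf (0.0583) and Fga (0.0844) did not pass. Fga, Hmgcs1 and Cyp51 also lost their calls in 14, 12 and 8 of 21 omissions. Their adjusted p reached 0.0863 and 0.078 (Fga and Cyp51, young 30 s library of animal 72) and 0.0788 (Hmgcs1, young 15 s library of animal 50). Age and submission batch cannot be told apart in these comparisons.

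At 15 s, where shorter coding sequences could be counted from codon 100 on, 2 genes of the Serpina3 family had the lowest changes among abundant genes in old liver. Serpina3b was at 1.89 ± 1.34 CPM (SD, n = 4) against 1439 ± 169 (n = 3), a change of -9.08 ± 0.30 (adjusted p = 2.52e-11), and Serpina3j changed by -5.11 ± 0.38. Both belong to a family of near-identical copies whose counts are uncertain. The acetyltransferase Nat8 (-2.73 ± 0.26), the desaturase Scd4 (-2.52 ± 0.46) and the carboxylesterase Ces1d (-2.42 ± 0.40) were lower as well. The highest were Serpina1f (2.46 ± 0.29) and, with coding lengths that differ between the gene sets, Mia2 (2.46 ± 0.19), Mgst1 (2.01 ± 0.28), the growth factor Igf1 (1.62 ± 0.23) and Atp6v0c (1.55 ± 0.31). Over the whole coding sequence Mgst1 (0.18, adjusted p = 0.762), Igf1 (0.76, 0.146) and Atp6v0c (0.67, 0.451) did not pass. Cholesterol synthesis had 0 of 21 genes called in limma, edgeR and DESeq2 (10 higher at an unadjusted p under 0.05, 9 higher adjusted over the list alone, median 0.50, camera adjusted p = 1.48e-08, adjusted p = 0.588 with an estimated correlation). Fdps was at 0.63 ± 0.19 (adjusted p = 0.165) and Hmgcs1 at 0.78 ± 0.26 (0.226). Gluconeogenesis had 1 of 11 lower (6 adjusted over the list alone, median -0.71, adjusted p = 0.00263, adjusted p = 0.428 with an estimated correlation). It was the aminotransferase Got1 (-0.78 ± 0.18, adjusted p = 0.0375; -0.59 and 0.239 over the whole coding sequence).

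ER chaperones had 0 of 18 called at 15 s in limma, edgeR and DESeq2 (3 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, median -0.24, camera adjusted p = 0.00709, adjusted p = 0.908 with an estimated correlation). P4hb was at -0.62 ± 0.20 (limma, adjusted p = 0.197; -0.72 and 0.0451 without the old library of animal 127) and Hspa5 at -0.04 ± 0.28 (adjusted p = 0.974; 0.04 in edgeR and DESeq2). Elongation factors had 0 of 11 called in limma, edgeR and DESeq2 (1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, median -0.05, adjusted p = 0.686). Eef1a1 was at -0.29 ± 0.23 (adjusted p = 0.66) and Eif5a at -0.49 ± 0.19 (0.31). In all 81 of 5516 genes passed in limma (29 higher, 52 lower), and 59 (17 higher, 42 lower) when genes of equal coding length alone were tested. The count was 53 (16 higher, 37 lower) without the old library of animal 119 and 41 without the young library of animal 51 (11 and 30) or of animal 71 (14 and 27). Without the old library of animal 108 or 111 it was 57 (15 and 42) or 56 (14 and 42). The call of Got1 ended in 6 of 7 omissions (adjusted p up to 0.134, animal 71), that of Atp6v0c without animal 108, 51 or 71 (up to 0.121, animal 51) and that of Scd4 without animal 50 or 71 (up to 0.078, animal 71). Adipocyte markers moved with old liver, with 2 of 5 higher (3 adjusted over the list alone, median 0.70, adjusted p = 0.00219, adjusted p = 0.498 with an estimated correlation).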

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

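The tests of other organs' reads in the muscle library of animal 26, of the kidney position of animal 72 and of genes with equal coding length were chosen only after the results had been seen. Samples are listed below because they stood apart from the rest of their group, which chance brings about in about 1 of 20 groups; 11 of 142 groups of gene values and 1 of 15 other groups had such a sample.

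Kidney proximal tubule transcripts stood at a median of 18.4 footprint CPM in untreated muscle of animal 26 and 1.42 in animal 27. Kidney tissue in that sample is argued against by its mRNA, where the list's median was 1.58 CPM against 1.49 in the other animals, a ratio of 1.06. Reads of other libraries stay open, since 2 of the 7 lists of other organs were at least 5 times as high as in animal 27 (kidney and lung, the latter at 7.01 against 0 CPM), and pancreas stood at 15 against 3.07 CPM. Transcripts held by muscle itself stay open too, though on the share of 1 library. The highest share of coverage on these genes among 8 muscle run-off libraries was 0.084%, against 0.226% in the animal 26 library (a ratio of 0.372) and 0.109% in that of animal 27. The other run-off libraries of muscle held 0.0169 to 0.0581%. The mRNA ratio gives no sign that muscle of animal 26 held more of these transcripts than the others. No difference between muscle and liver in these genes may be read from the 2 libraries while these stay open.

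The young liver library of animal 72 at 30 s reached codon 215, against 166 and 152, and its kidney library at 30 s had a missing area of 78.8 codons, against 54.5 to 56.5 in the other 3. Reads of kidney or muscle libraries are argued against, since markers of both held 0.0516% of its coverage and up to 0.0606% of that of the other 8 young liver libraries at 15 to 45 s, a ratio of 0.85 (at 60 s up to 0.0737%). Transcripts with few footprints are argued against as well, because the gap to the next library was 48.2 codons with 200 footprints or more per transcript and 48.4 with 50. An earlier injection or faster uptake in the whole animal is a candidate explanation that stays open: the divided kidney position of animal 72 led the next by 17.2 codons, a lead that 1 of 4 animals has by chance, but its muscle position, 84.2, lay between 73.6 and 89. No biological explanation was tested.

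Between old and young liver 313 genes passed from codon 350 on. Coding sequences of another length in the 2 sets of files are argued against for the 280 genes that passed when genes of equal coding length alone were tested. That test could hardly lose most calls, since 5180 of the 5611 genes in both sets had the same length. It leaves other differences between the 2 sets untested. At 15 s another length stays open, where a separate fit of genes of equal length called 59 (17 higher), beside 81 (29 higher) with all genes. Only the real split gave as many, 1 of 100 (highest other 1) and at 15 s 1 of 35 (highest other 0). Other splits mix the ages, so they cannot decide on chance. Age and the submission batch cannot be told apart, because 0 old libraries came with the set of genes of the young ones. Age remains an open explanation, as untested.

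Untreated liver footprints of animal 27 held more of 5 kidney genes than any other liver library, Lrp2 at 13.3 CPM (next 4.45), Miox at 3.61 (0.172), Cubn at 0.784 (0), Slc12a1 at 0.47 (0) and Slc12a3 at 0.157 (0), values of 1 library and so not independent. In liver footprints of animal 26 Vsig4 stood at 43.9 CPM, next to 30.6. The old 15 s library of animal 127 held 4417 CPM of Itih3 (next 2516), 21504 of Fga (8750) and 76 of Masp1 (124) from codon 350 on. Eef1a1 was at 1149 CPM in the old 30 s library of animal 118 and at 1940 in the nearest other. Mia2 was at 379 CPM in the old 15 s library of animal 119 and at 348 in the next.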

How the results depend on the processing

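Chosen only after the data had been seen were the alternatives of the divided position and of the missing area, the removal of group means, the clipping of the area and its signed form, edgeR on rounded footprint equivalents, genes of equal coding length, lists without the muscle library of animal 26 and the estimated correlation. Of values under other settings, 32 of 43 rates by the fixed rule (9 stronger, 2 reversed), 37 of 46 of their differences (1 stronger, 8 reversed), 38 of 38 divided rates, 31 of 31 rates by area, 44 of 45 divided differences, 33 of 38 differences by area, 34 of 41, 29 of 35 and 24 of 29 abundance differences (fixed, divided and by area; all others reversed) and 1400 of 1534 values of named genes (118 weaker, 6 stronger, 10 reversed) kept their direction and side of the threshold. Of 16 start codon shares under other settings 1 stayed within the 95% Wilson interval of the share in its file, which covers counting error only. With 1 library left out, 2121 of 2257 values of named genes kept their direction and side of the threshold. Where a result changed, the cause was not tested unless a stricter threshold or fewer libraries or genes gave it. Depth limits the transcripts behind a profile: with 1000 codons or 200 footprints no abundance difference could be had in young liver, and crossings from the lowest point of undivided profiles were missing in 13 of 41 libraries.

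The undivided rate of muscle passed at level 0.6 (4.66 codons per s), with 200 footprints (4.53), weighting by footprints (4.49), smoothing over 51 codons (4.24) and 15 to 60 s (3.18). Muscle minus kidney reached 4.94 with 200 footprints (adjusted p = 0.0218 by permutation), muscle minus liver -0.270 with weighting (0.94) and kidney minus liver 0.163 at 15 to 60 s (0.755). Rates of young liver, kidney and muscle were 5.95, 4.10 and 3.31 by area and 6.94, 5.15 and 4.13 divided. Muscle minus liver, muscle minus kidney and old minus young were -2.64, -0.790 and -0.818 by area and -2.81, -1.02 and -1.08 divided. Undivided old minus young ranged from 5.73 to 6.30 with 1 library left out.

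With group means removed, where the permutation p is approximate, muscle minus liver passed at -2.81 divided (adjusted p = 0.009, over its alternatives 0.009 to 0.62). By area it passed at -2.64 (0.01, over its alternatives 0.004 to 0.5), and kidney minus liver at -1.85 (0.0212, over its alternatives 0.0212 to 0.375). Without that removal, muscle minus liver by area passed with weighting by footprints (-2.32, 0.046) and with a signed area (-3.86, 0.004), and kidney minus liver on the divided profile (-1.81, 0.0392). With the animal as a block, over fewer libraries, undivided kidney minus liver, muscle minus liver and muscle minus kidney were -0.409, 2.29 and 2.90 codons per s (exact, adjusted p = 1 each). Divided differences in these blocks were -1.31, -2.36 and -1.07 (exact, adjusted p = 0.188, 0.62 and 0.62), and by area -1.53, -2.35 and -0.760 (exact, adjusted p = 0.375, 0.5 and 0.5). Blocked gene counts were 6095 and 8137 for footprints of kidney and muscle, 11519 and 12764 for mRNA and 698 and 3983 for translation efficiency. Apart from Slc5a12 footprints in muscle and the 6 translation efficiency calls in kidney given above, the block changed no call among named genes. The 9 blocked rate differences counted above say nothing about stability, since exact sign flips could not give an adjusted p under 0.0938 for kidney minus liver or 0.125 for the others. Lists were not tested with the block, nor was it combined with removed group means. For the age comparisons, no paired analysis was possible because old and young animals share no number.

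High minus low abundance never passed and changed sign in some settings. Undivided kidney turned to 0.838 at level 0.6, 2.64 with 200 footprints, 0.674 with 51 codons, 0.607 by area and 0.111 divided. Undivided old liver turned to -0.191 with 200 footprints and muscle to -0.0372 at 15 to 60 s. Divided young liver turned to 5.35 at level 0.4. Divided kidney turned to -0.0375 at level 0.6, -0.0449 with 1000 codons, -0.201 with 200 footprints, -0.0268 with common transcripts and -2.53e-05 at 15 to 60 s, and ranged from -0.0607 to 0.178 with 1 library left out. By area, old liver turned to -0.460 with 200 footprints, -0.668 signed and -0.146 on the divided profile, muscle to -0.818 at 15 to 60 s and kidney to -0.544 signed.

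Start codon shares over codons 1 to 10 were 8.14% in brain, 51.1% in heart, 46.2% in kidney, 18.3% in liver, 44.1% in lung, 47.2% in muscle, 65.3% in pancreas and 33.9% in testis. With equal weight per coding sequence they were 4.66% in brain, 25.5% in heart, 23.6% in kidney, 16.1% in liver, 22.9% in lung, 25.4% in pancreas and 17% in testis.

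Eef2 footprints in muscle were 0.09 with RLE, 0.07 with 2 organs and 0.09 in DESeq2, and -0.11 to 0.06 with 1 library left out. Translation efficiency in kidney was -0.07, -0.04 and -0.08 for Eef1a2 in those settings (-0.50 to 0.55 with 1 library left out) and -0.02 for Eif5a with RLE and in DESeq2. In muscle, Amn ranged from -2.65 to 6.72 and Slc13a1 from -4.20 to 9.55 with 1 library left out. These ends but 6.72 are fitted with 0 footprints in an organ, where 9.55 stands for at least 17.2-fold higher. Hspa5 at 15 s was 0.04 in edgeR and DESeq2 and ranged from -0.24 to 0.17. At 2-fold or more, 6736 genes of 11609 passed in kidney mRNA, 444 of 879 and 2845 of 4471 in translation efficiency of kidney and muscle, and 35 of 313 between ages from codon 350 on. Kidney translation efficiency gave 879 genes in edgeR, 1493 in DESeq2 and 403 to 1210 with 1 library left out. Between ages 169 genes, against 313, passed from codon 500 on, and 25, 7 and 103 at 15, 30 and 45 s alone. The 15 s count of 81 ran from 41 to 87 with 1 library left out. With an estimated correlation 10 of the 140 list results of comparisons with liver or between ages that passed at the preset one did. Lists of an organ set against the mean of the other organs are not counted there.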

Other observations

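The estimated correlation of list tests was chosen only after the data had been seen. Footprints of each other organ, set against the mean of the remaining ones in edgeR, were higher for its own marker genes. In brain 30 of 30 measured markers were higher (30 adjusted over the list alone, median log2 fold change 9.28), in heart 25 of 25 (25 adjusted over the list alone, median 10.89), in lung 25 of 25 (25 adjusted over the list alone, median 11.15) and in spleen 27 of 27 (27 adjusted over the list alone, median 7.14). Pancreas had 29 of 29 higher (29 adjusted over the list alone, median 15.84) and testis 28 of 28 (28 adjusted over the list alone, median 13.04). With an estimated correlation the adjusted p was 0.0211 in brain, 0.0125 in heart, 0.00682 in lung, 0.0147 in spleen, 0.0303 in pancreas and 0.178 in testis. In mRNA the medians were 8.53 in brain (30 of 30 higher, 30 adjusted over the list alone), 10.43 in heart (25 of 25, 25 adjusted over the list alone), 10.50 in lung (25 of 25, 25 adjusted over the list alone), 19.10 in pancreas (31 of 31, 31 adjusted over the list alone) and 10.88 in testis (28 of 28, 28 adjusted over the list alone). There the call was lost in pancreas (adjusted p = 0.0607 with an estimated correlation) and testis (adjusted p = 0.522 with an estimated correlation). Podocyte genes were mixed in kidney footprints, 6 of 10 higher and 2 lower (6 and 2 adjusted over the list alone, median 1.55, camera adjusted p = 0.151), and slow sarcomere genes in muscle, 7 of 10 higher and 2 lower (7 and 2 adjusted over the list alone, median 2.38, camera adjusted p = 0.222).

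Bile acid synthesis and transport genes were lower than in liver in footprints of kidney (14 of 15 lower and 1 higher, 14 and 1 adjusted over the list alone, median -8.64, adjusted p = 0.00569 with an estimated correlation) and of muscle (15 of 15, 15 adjusted over the list alone, median -7.96, adjusted p = 0.00906 with an estimated correlation). The urea cycle was lower in muscle in 8 of 8 genes (8 adjusted over the list alone, median -7.70, adjusted p = 0.0441 with an estimated correlation), and male-biased liver genes in 18 of 22 (20 adjusted over the list alone, median -7.37, adjusted p = 0.0441 with an estimated correlation). Excitation and calcium handling genes were higher in muscle in 19 of 20 (20 adjusted over the list alone, median 12.31, 10.99 with genes at 0 set to their bound, adjusted p = 0.037 with an estimated correlation). In mRNA these had a median of 9.89 in muscle (9.78 at the bound, 19 of 20 higher, 19 adjusted over the list alone), fast sarcomere genes 10.02 (29 of 29, 29 adjusted over the list alone) and, in kidney, distal nephron genes 9.15 (9.03 at the bound, 28 of 28, 28 adjusted over the list alone). In liver mRNA the excitation genes stood at a median of 0.101% of their muscle level and the distal nephron genes at 0.137% of their kidney level. Their adjusted p was 0.000741, 0.000741 and 0.0027 with an estimated correlation. Genes of the interferon response were lower in kidney footprints in 18 of 28 (18 adjusted over the list alone, median -1.80, camera adjusted p = 9.4e-08, adjusted p = 0.0872 with an estimated correlation). In muscle footprints 17 of these 28 were lower and 5 higher (18 and 5 adjusted over the list alone, median -1.19, camera adjusted p = 0.00217, adjusted p = 0.353 with an estimated correlation).

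Untreated spleen footprints had 1.44 to 1.65% of coding footprints in codons 1 to 5 (n = 3). In mRNA, 11609 genes passed between kidney and liver and at most 0 in any other split of the same libraries, and 12805 between muscle and liver and at most 0, where the real split was 1 of 10. With 3 libraries against 3, splits are too few for a share under 0.05.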
